A study of Gallus gallus with 10 samples.

How the data were processed

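RNA from the choroids of normal chicks at day 15 after hatching was extracted with TRIzol, selected for poly(A) and made into strand-specific libraries from 100 ng of RNA, per the labels. There were 10 libraries, 5 with PAPA-NONOate and 5 controls, grouped by their titles, with the replicate numbers 2, 3, 4, 5 and 8 in both groups. The deposited values are FPKM, fragments normalized to transcript length and to the library total, in 1 table of 24355 genes with chicken Ensembl identifiers. Per the submitters' processing notes, Cufflinks and SAMtools were used with the genome build GRCg6a. Their versions, the aligner and the annotation release are not given in the sources used here. Of the genes 13556 carry a common name and 10799 do not, 7 names had been turned into dates and were not used as names, and 288 share their name with another gene. In all 14 values of 10 genes stand at 999999999, which was read as a failed estimate and treated as missing, and 5078 genes are listed at 0 in every library. A 0 in such a table can also be a failed estimate. Near-identical genes can share fragments, and how these were divided is not given in the sources used here.

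FPKM give no depth. From the steps between low values (under 0.15 FPKM, matched within 0.1 on the log2 scale) the relative depth was 0.663 to 1 of that of control replicate 2, and the absolute depth is unknown, so that no counting intervals are given. Correlations between libraries of a group ran from 0.930 to 0.978, and no pair was treated as a duplicate.

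The test was limma 3.58.1 (R 4.3.3, with a mean-variance trend) on log2(FPKM + 0.5), for the 11357 genes with an FPKM of at least 1 in at least 5 libraries. It had 8 residual and 4.83 prior degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Adjusted p-values of genes are from limma unless another test is named. In all, 34 gene lists of pathways and cell type markers, with 870 symbols of which 743 were found by exact name, were tested with camera where at least 5 members were measured. Camera compares a list with all other genes and was run with a correlation of 0.01 between genes, then with a correlation estimated for each list, and fry was run on the same lists. Single values of libraries were compared by exact permutation tests, two-sided. The tests, the gene lists, the filter, the alternatives and the rule for named genes were fixed before the data were examined, except where said otherwise. The rule named, among called genes with a symbol, a mean of at least 2 FPKM in the higher group and no overlap of the groups, the 12 largest rises and the 12 largest falls. It added from each called list up to 4 members, and from other lists up to 2, with the smallest adjusted p. IL6, ALDH1A2, APOA1, NOS2, NOS1, NOS3, GUCY1A1, GUCY1B1, HMOX1, VEGFA, BMP2, PECAM1, MYH11, TYR, RPE65 and HBAD were among the genes given whatever their values. This made 121 genes, of which 119 were tested. Some genes that the rule takes in are not reported here, and they are left out of these counts but not out of the lists.

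Alternatives were pseudocounts of 0.1 and 1, no filter, a filter at 5 FPKM, median-ratio scaling, quantile normalization, library weights, the replicate number as a block (also with quantile normalization), each library left out in turn, limma without the trend or with robust estimates, an exact Wilcoxon test per gene, and camera on ranks. Median-ratio scaling with PAPA-NONOate replicate 2 left out or with the block, the block with camera and an estimated correlation, and an exact permutation test of list levels, were added after the data were seen. The test was tried on simulated data for this comparison, with 50 of 11357 genes changed at each size. It recovered 18% of them at a log2 fold change of 0.5, 66% at 1, 92% at 1.5 and 96% at 2, and 5 of 141 calls (3.55%) were of unchanged genes. The simulated genes varied independently, without differences between libraries that many genes share, so these shares need not hold for the real libraries. Neighbouring genes were taken from a RefSeq table of another assembly (GRCg7b), in which 8858 named genes had a place, and no coordinates are given. Figures were drawn with matplotlib 3.10.9.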

Results

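Gene expression was measured by RNA sequencing of poly(A)-selected RNA from chick choroid, the pigmented vascular layer between retina and sclera. The tissue came from normal eyes of chicks at day 15 after hatching. PAPA-NONOate is a small molecule that releases nitric oxide as it decays, and the study asked how nitric oxide changes choroidal gene expression. It compared 5 choroids kept with the donor at 1.5 mM (37 °C, 5% CO2, 24 hours) with 5 control choroids. The labels give the same incubation text for both groups and call the controls minus PAPA-NONOate. They do not say that replicates came from separate animals, so p-values measure the spread between these samples. They also mark every treated sample with the letter R and every control with the letter L, without saying what the letters are, so that whatever they mark is confounded with the treatment. The deposited table lists 24355 genes as FPKM (fragments normalized to transcript length and to the library total), of which 11357 reached an FPKM of 1 in at least 5 libraries and were tested. Read counts are not in the files used here and the absolute depth is unknown. The steps between low values put the relative depth of the libraries within 1.51-fold of each other, with means of 0.756 with PAPA-NONOate and 0.841 in controls relative to control replicate 2 (exact two-sided permutation p = 0.317, n = 5 per group). Genes at an FPKM of 1 or more numbered 11083 ± 80.8 with PAPA-NONOate and 11421 ± 74.8 in controls, without overlap (SD, n = 5 per group, exact two-sided permutation p = 0.00794). The highest summed FPKM (control replicate 8) was 1.53 times the lowest (PAPA-NONOate replicate 2), and transcripts of the mitochondrial genome took 17.9 to 24.8% of each sum.

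After PAPA-NONOate the heat shock genes HSPB9 and HSPA2, the interferon-stimulated genes IFIT5, IFI6 and MX1, the immediate early genes FOSB and NR4A3 and 13 genes of sterol synthesis and uptake were higher than in control choroids. In contrast, 22 of 23 measured genes of the cell cycle and DNA replication list and 8 markers of macrophages and myeloid cells were lower. In all, 1061 genes passed a Benjamini-Hochberg adjusted p of 0.05 in limma, 219 higher and 842 lower, and 435 of them changed at least 2-fold, 95 higher and 340 lower. The median gene was itself lower with PAPA-NONOate, by a log2 fold change of -0.18. After median-ratio scaling of the libraries 1539 genes passed, 790 higher and 749 lower. After quantile normalization 733 were higher and 680 lower. All 219 genes called higher and 695 of the 842 called lower as deposited kept call and direction after median-ratio scaling. Mean FPKM ± SD are given for PAPA-NONOate against control. Log2 fold changes of genes are given as deposited, on the log2(FPKM + 0.5) scale, which understates the change of weakly expressed genes. Medians of gene lists are given relative to the median of all genes. Counts of list members that rose or fell are as deposited, and some of them change with the scaling. The groups did not overlap for 1058 genes (9.32% of those tested, where 0.794% would be so by chance). The number of calls depended on the libraries included: it was 693 without PAPA-NONOate replicate 3 and 1813 without PAPA-NONOate replicate 5, and 604, 707, 684 and 689 without control replicate 2, 3, 4 or 8. Genes called lower numbered 529, 1580, 429, 549, 517 and 501 in these 6 cases, and those at least 2-fold lower 517 without PAPA-NONOate replicate 5. PAPA-NONOate replicate 2 lay farthest from the other libraries on the first principal component (44.6% of the variance, at 65.2), with the lowest summed FPKM. PAPA-NONOate replicate 5 lay at -10.0 on it, next to control replicate 5 (-11.3), while the other treated libraries lay at 18.8 to 65.2.

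Among called genes with a symbol, a mean FPKM of at least 2 in the higher group and no overlap between the groups, the largest rises were those of LSMEM1 (log2 fold change 2.97, SE 0.33, adjusted p = 0.000328), HSPB9 and STEAP4. HSPB9 (ENSGALG00000023818), of the small heat shock protein family, was at 820.1 ± 373 against 101 ± 31.4 FPKM (SD, n = 5), a log2 fold change of 2.95 (SE 0.30, adjusted p = 0.000208). STEAP4, a metalloreductase of the cell membrane and endosomes, was at 24.7 ± 8.48 against 3.03 ± 1.61 FPKM (SD, n = 5), with a log2 fold change of 2.85. ANKRD1 (2.33), the aryl hydrocarbon receptor target CYP1A1 (2.23) and the endothelial lipase gene LIPG (2.05) were also among the 12 largest, with log2 fold changes in parentheses and adjusted p-values of 0.000449, 0.00212 and 0.000156. In every control LSMEM1, ANKRD1 and CYP1A1 lay below the pseudocount of 0.5 FPKM, so that the size of their changes depends on it. LSMEM1 was at 5.96 ± 3.80 against 0.244 ± 0.160 FPKM (SD, n = 5), and its log2 fold change ran from 2.34 to 4.08 over the settings. By the same rule the largest falls were those of CDCA3 (log2 fold change -3.26, SE 0.38, adjusted p = 0.000445) and SMC2 (-3.00), a subunit of condensin. Outside the cell cycle they included DGUOK, the mitochondrial deoxyguanosine kinase, with a log2 fold change of -2.59 (SE 0.28, adjusted p = 0.000296). They also included the fatty acid and scavenger receptor gene CD36, at 2.29 ± 0.522 against 14.7 ± 3.40 FPKM (SD, n = 5), the transporter gene SLC7A14 (log2 fold change -2.39) and IL17REL (-2.04). That the groups do not overlap in these genes follows from the rule. Each of these genes kept its call and direction in limma under those of the 21 settings run for named genes in which it could be tested. The exact Wilcoxon test per gene called 0 genes, with 2352 at an unadjusted p under 0.05 (3194 by limma).

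**Figure D1:**
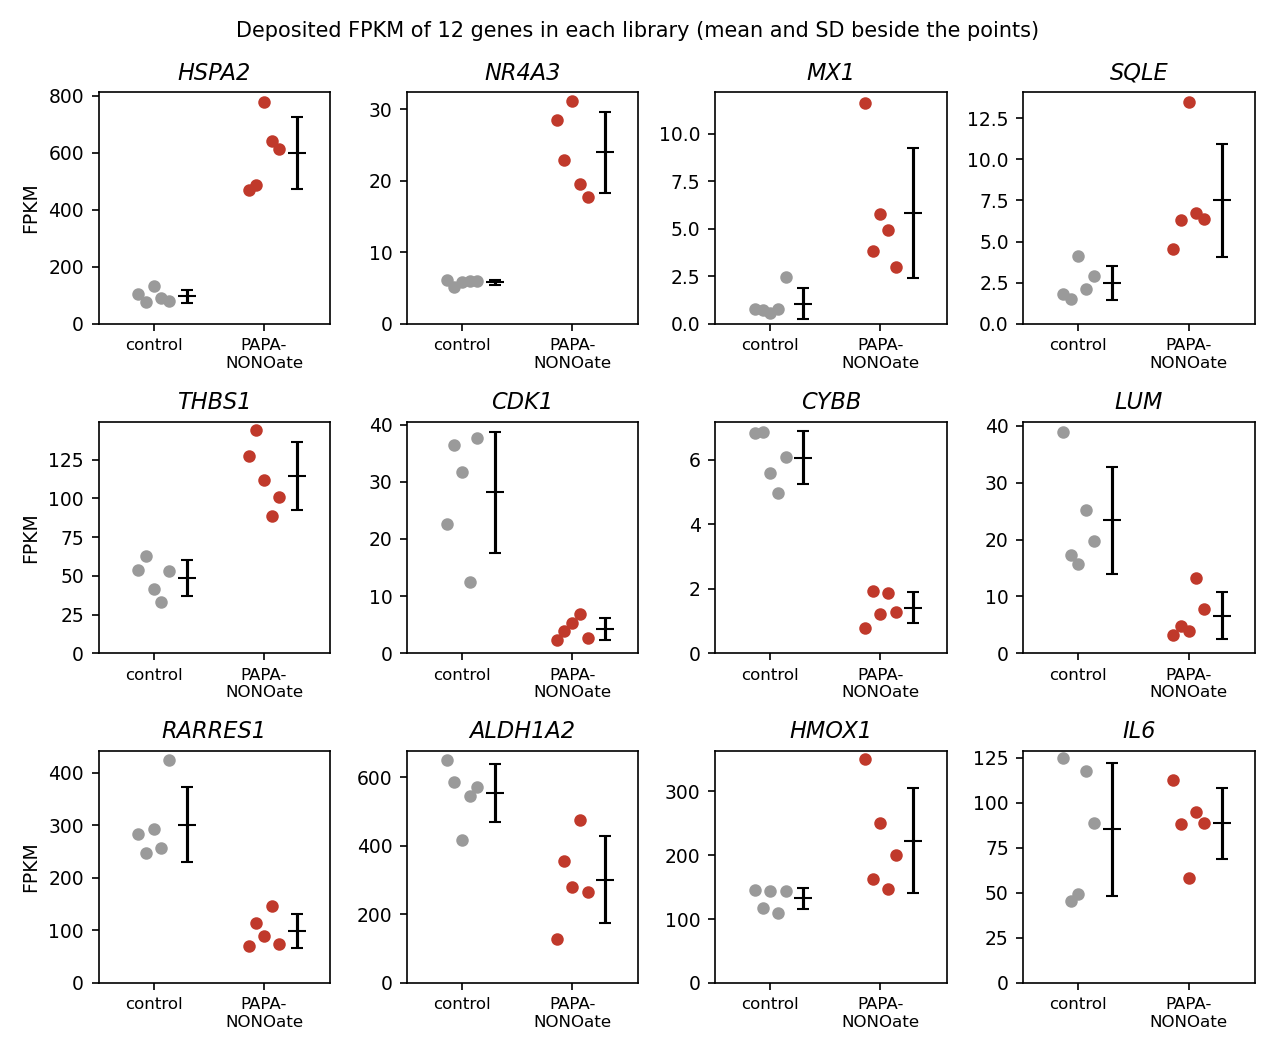
FPKM as deposited of 12 genes in the 5 control libraries (grey) and the 5 libraries with PAPA-NONOate (red), on linear axes that start at 0; the bar beside each group is the mean with its SD. HSPA2 was at 598 ± 125 against 96.5 ± 23.1 FPKM, and CDK1 at 4.23 ± 1.88 against 28.2 ± 10.6 FPKM, whereas the groups overlapped for IL6, and for ALDH1A2 1 treated library lay above the lowest control.

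Single genes of the heat shock and antioxidant responses were much higher with PAPA-NONOate, while most members of these lists did not pass. HSPA2 (ENSGALG00000011715), a heat shock chaperone, had a log2 fold change of 2.63 (SE 0.18, adjusted p = 3.01e-05). HSPB9, with a log2 fold change of 2.95, is not in the list of heat shock chaperones. For the heat shock chaperones, of 23 measured members 2 rose, 1 fell and 20 did not pass (2 and 1 adjusted over the list alone). The other 2 calls were BAG3, a co-chaperone (0.39), and the small heat shock gene CRYAB (-0.99), and the log2 fold change of DNAJA4 was 0.35 (adjusted p = 0.102). DNAJA4 passed after median-ratio scaling, after quantile normalization or with library weights. The list was higher than other genes (adjusted p = 0.00546 by camera, and adjusted p = 0.822 with an estimated correlation), with a median of -0.01 and a mean of 0.08 as deposited, which differ in sign. This call was lost without the expression filter. The NRF2 antioxidant list lay above other genes, with a median of 0.21 relative to all genes (adjusted p = 0.000734 by camera, and adjusted p = 0.608 with an estimated correlation). Of 24 measured members 3 rose, 1 fell and 20 did not pass (4 and 1 adjusted over the list alone). Those that rose were TXNRD1, thioredoxin reductase, with a log2 fold change of 1.27 (SE 0.25, adjusted p = 0.00823), the cystine transporter gene SLC7A11 (1.34) and NQO1 (0.55), and the member that fell was the catalase gene CAT (-0.53). HMOX1, heme oxygenase, was at 223 ± 82.5 against 132 ± 16.9 FPKM (SD, n = 5), with a log2 fold change of 0.69 (adjusted p = 0.0612) and all 5 treated libraries above the controls. It passed after median-ratio scaling (adjusted p = 0.0487), with library weights, with the replicate number as a block or without PAPA-NONOate replicate 5. For the p53 and DNA damage list, of 20 measured members 2 rose, 0 fell and 18 did not pass (2 and 0 adjusted over the list alone), the 2 being CDKN1A, an inhibitor of cyclin-dependent kinases (log2 fold change 0.84, SE 0.19, adjusted p = 0.0186), and CCNG1 (0.50). This list lay 0.23 above all genes by its median (adjusted p = 0.00401 by camera, and adjusted p = 0.595 with an estimated correlation), a call lost without the expression filter. The log2 fold changes of GADD45B (0.53) and TNFRSF10B (0.61) did not pass, that of GADD45B except after either scaling, with library weights or without control replicate 8. The unfolded protein and integrated stress response list was not called (adjusted p = 0.687 by camera, and adjusted p = 0.975 with an estimated correlation). Of 26 measured members 3 rose, 5 fell and 18 did not pass (4 and 6 adjusted over the list alone), with the rise of ATF3 (0.61) and the fall of CRELD2 (-0.92) among the calls. NQO1 lost its call without the expression filter and without PAPA-NONOate replicate 3 or 4 or control replicate 3, 4, 5 or 8 (adjusted p up to 0.0826). CAT lost its call without the expression filter and without PAPA-NONOate replicate 2, 3, 4 or 8 or any control replicate (adjusted p up to 0.110). CRYAB lost its call without the expression filter, after median-ratio scaling, after quantile normalization and without PAPA-NONOate replicate 3 or 4 or any control replicate (adjusted p up to 0.142). BAG3 lost its call with the stricter filter and without PAPA-NONOate replicate 3, 4 or 8 or any control replicate (adjusted p up to 0.0985). CCNG1 lost its call without PAPA-NONOate replicate 4 or 8 or control replicate 3 or 4 (adjusted p up to 0.0649). With the replicate number as a block NQO1, CAT, BAG3 and CCNG1 also lost their calls.

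Interferon-stimulated genes were higher as a list with PAPA-NONOate. Of 22 measured members 9 rose, 0 fell and 13 did not pass (14 and 0 adjusted over the list alone). The median of the list lay 0.60 above that of all genes (adjusted p = 7.70e-17 by camera, and adjusted p = 0.14 with an estimated correlation). IFIT5 (ENSGALG00000045085), of an antiviral RNA-binding family, was at 143 ± 72.3 against 33.3 ± 14.4 FPKM (SD, n = 5), with a log2 fold change of 2.06 (SE 0.30, adjusted p = 0.00169). MX1, an antiviral GTPase, had a log2 fold change of 1.99 (adjusted p = 0.00424), IFI6 of 2.02, CMPK2 of 1.6 and the RNA helicase gene ZNFX1 of 0.78. The list of inflammatory cytokines and chemokines also holds genes of intracellular regulators, IRF1 and NFKBIZ among them. Of its 21 measured members 6 rose, 0 fell and 15 did not pass (7 and 1 adjusted over the list alone). Their median lay 0.32 above all genes (adjusted p = 7.17e-06 by camera, and adjusted p = 0.190 with an estimated correlation). CCL19, a lymphoid chemokine gene, rose and was at 18.1 ± 12.0 against 3.12 ± 1.20 FPKM (SD, n = 5), with a log2 fold change of 2.13 (SE 0.43, adjusted p = 0.00928). Others that rose were CX3CL1 (0.87), the interferon regulatory factor gene IRF1 (log2 fold change 0.90, SE 0.11, adjusted p = 0.000617) and NFKBIZ (0.55). IL6 (ENSGALG00000010915), the inflammatory cytokine, was at 88.6 ± 19.6 against 85.3 ± 37.0 FPKM (SD, n = 5). This difference was less than the spread between replicates, a log2 fold change of 0.15 with a 95% interval of -0.47 to 0.76 (adjusted p = 0.771). In the same comparison the markers of macrophages and myeloid cells had a median log2 fold change of -0.52 relative to all genes, and in PAPA-NONOate replicate 2 the interferon list stood highest. The call of NFKBIZ was lost without PAPA-NONOate replicate 4 or control replicate 2, 4 or 8 (adjusted p up to 0.0620).

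Immediate early genes, which respond to stimuli without new protein synthesis, were higher as a list after the 24 hours of incubation. Of 24 measured members 12 rose, 0 fell and 12 did not pass (12 and 0 adjusted over the list alone). Their median lay 0.60 above that of all genes (adjusted p = 6.81e-17 by camera, and adjusted p = 0.14 with an estimated correlation). NR4A3 (ENSGALG00000013568), an orphan nuclear receptor, was at 24.0 ± 5.72 against 5.82 ± 0.358 FPKM (SD, n = 5), with a log2 fold change of 1.92 (SE 0.16, adjusted p = 3.79e-05). FOSB had a log2 fold change of 2.10 (adjusted p = 0.000440), CYR61, a matricellular protein, of 1.80 and FOS of 1.0. Sterol genes were higher as well. Of 21 measured members 13 rose, 0 fell and 8 did not pass (14 and 0 adjusted over the list alone). All 21 lay above the median of all genes, the median of the list by 1.04 (adjusted p = 1.11e-19 by camera, and adjusted p = 0.208 with an estimated correlation). Per library, the level of the list (mean log2 value of its members less the library's median) was highest in PAPA-NONOate replicate 4, at 1.36 against 0.49 to 0.73 in the other treated libraries. FDFT1 and SREBF2 were also highest there, at 20.2 and 83.4 FPKM. SREBF2, the transcription factor that drives this pathway, was at 56.5 ± 19.6 against 22.5 ± 4.18 FPKM (SD, n = 5), with a log2 fold change of 1.25 (SE 0.23, adjusted p = 0.00537). The log2 fold changes of the enzyme genes SQLE, FDFT1 and HSD17B7 were 1.40, 1.21 and 1.28, with adjusted p-values of 0.00892, 0.00509 and 0.00537. Of 23 angiogenic factors only ANGPT2, an endothelial growth factor that binds the receptor TIE2, rose, with a log2 fold change of 0.99 (SE 0.19, adjusted p = 0.00795), none fell and 22 did not pass (the same counts adjusted over the list alone). The list lay 0.21 above all genes by its median (adjusted p = 0.00546 by camera, and adjusted p = 0.404 with an estimated correlation), a call lost without the expression filter and after quantile normalization. VEGFA was at 183 ± 62.6 against 229.8 ± 46.9 FPKM (SD, n = 5; log2 fold change -0.36, adjusted p = 0.257). HGF (0.63), JAG1 (-0.49) and PDGFD (0.35) did not pass as deposited. HGF passed after either scaling or without control replicate 5, PDGFD after median-ratio scaling, and JAG1 with library weights or without PAPA-NONOate replicate 5.

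**Figure D2:**
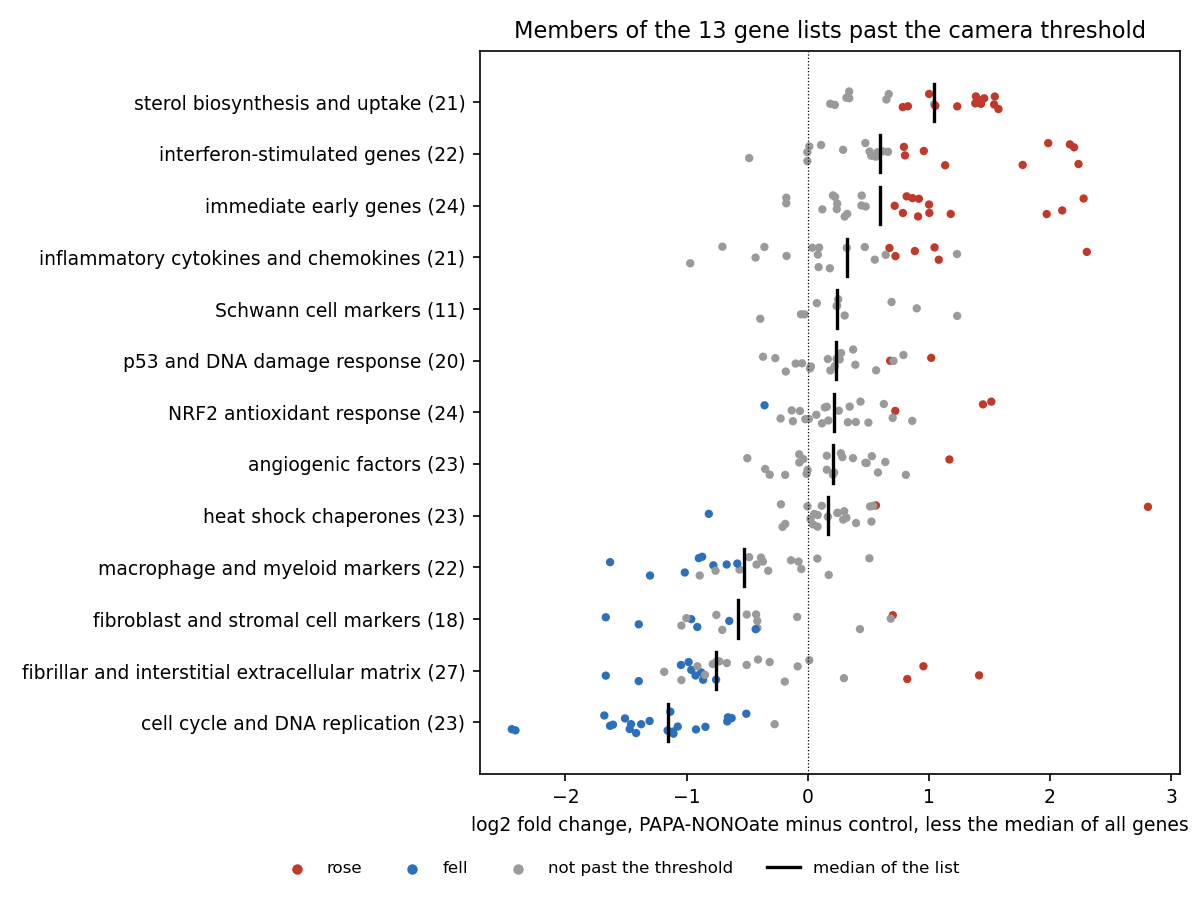
Log2 fold changes of the members of the 13 gene lists past the camera threshold, each less the median of all genes (dotted line at 0); each point is a gene, the number in parentheses is the number of members measured and the black bar is the list's median. The medians run from -1.16 for the cell cycle list to 1.04 for the sterol list. Within the heat shock list a single gene, HSPA2, lies far from the other members, and HSPB9 is not in that list.

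Genes of cell division and DNA replication were lower in the treated choroids. Of 23 measured members 0 rose, 22 fell and 1 did not pass (0 and 23 adjusted over the list alone). The list had a median of -1.16 relative to all genes (adjusted p = 3.02e-18 by camera, and adjusted p = 0.208 with an estimated correlation). Among controls its level was lowest in replicate 5 (-1.23, against -0.75 to -0.38 in the others), and with PAPA-NONOate it ran from -2.10 to -1.75. In the same comparison macrophage and fibroblast markers had medians of -0.52 and -0.57 relative to all genes. The member that did not pass over all genes, named after its value was seen, was PCNA, with a log2 fold change of -0.45 (adjusted p = 0.0903). RRM2, the regulatory subunit of ribonucleotide reductase, was at 3.20 ± 0.679 against 23.1 ± 7.51 FPKM (SD, n = 5), with a log2 fold change of -2.62 (SE 0.24, adjusted p = 0.000142). CDK1 (ENSGALG00000003085), the mitotic kinase, was at 4.23 ± 1.88 against 28.2 ± 10.6 FPKM (SD, n = 5), with a log2 fold change of -2.59. KIF11, a spindle motor, and MCM3, of the replicative helicase, had log2 fold changes of -1.81 and -1.64 (adjusted p = 0.000710 and 0.000764). Genes of division outside the list also stood among the largest falls: UBE2C (-2.34), which acts in the ubiquitylation of mitotic proteins, the centromere gene CENPW (-2.18) and the cytokinesis gene ANLN (-2.11). So did KPNA2 (-2.10), a nuclear import receptor.

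As a list, extracellular matrix genes were called lower by camera with its preset correlation, with exceptions. Of 27 measured members 9 fell, 15 did not pass and 3 rose (17 fell and 3 rose adjusted over the list alone). The list had a median of -0.76 relative to all genes (adjusted p = 0.0225 by camera, and adjusted p = 0.889 with an estimated correlation). This call was lost with library weights and without PAPA-NONOate replicate 4 or 8 or control replicate 5 (adjusted p up to 0.105 with 1 library left out). The matrix list did not pass fry (adjusted p = 0.101) or the exact permutation test of list levels (adjusted p = 0.0847). LUM, the small proteoglycan lumican, was at 6.60 ± 4.12 against 23.4 ± 9.42 FPKM (SD, n = 5), with a log2 fold change of -1.84 (SE 0.34, adjusted p = 0.00563). DCN, decorin, had a log2 fold change of -1.14 and TNC, tenascin C, of -1.10. The 3 that rose were THBS1, thrombospondin, with a log2 fold change of 1.24 (SE 0.18, adjusted p = 0.00194), VCAN (0.64) and COL12A1 (0.78), of which VCAN and COL12A1 are named after their values were seen. Fibroblast and stromal markers, which share LUM, DCN, COL1A1, COL1A2 and COL3A1 with the matrix list, had a median of -0.57 relative to all genes (adjusted p = 0.0419 by camera, and adjusted p = 0.889 with an estimated correlation). Their call was lost with the stricter filter, with library weights and without PAPA-NONOate replicate 4 or 8 or control replicate 3 or 5 (adjusted p up to 0.128). Of 18 measured members 1 rose, 6 fell and 11 did not pass (2 and 13 adjusted over the list alone), SFRP2 at -0.61 and PRRX1 at -0.82 among those that fell. Matrix proteases and inhibitors were not called as a list (adjusted p = 0.751 by camera, and adjusted p = 0.975 with an estimated correlation). Of 20 measured members 1 rose, 4 fell and 15 did not pass (2 and 5 adjusted over the list alone). MMP1, interstitial collagenase, was at 420.1 ± 122 against 141 ± 59.8 FPKM (SD, n = 5), with a log2 fold change of 1.61 (SE 0.26, adjusted p = 0.00280). MMP9, a gelatinase, had a log2 fold change of -1.21. For the basement membrane list camera gave an adjusted p = 0.687, and adjusted p = 0.975 with an estimated correlation. Of 12 measured members 0 rose, 2 fell and 10 did not pass (0 and 2 adjusted over the list alone), the falls being those of LAMA4 (-0.89) and COL18A1 (-0.58). PRRX1 lost its call without the expression filter and without PAPA-NONOate replicate 4 or control replicate 2, 3, 4 or 8 (adjusted p up to 0.0728). MMP9 lost its call without the expression filter and without PAPA-NONOate replicate 4 or 8 or control replicate 2, 3, 5 or 8 (adjusted p up to 0.0727). LAMA4 lost its call without the expression filter, after quantile normalization and without PAPA-NONOate replicate 2, 3 or 4 or control replicate 2, 3, 4 or 5 (adjusted p up to 0.0859). COL18A1 lost its call without the expression filter, with the stricter filter, after median-ratio scaling, after quantile normalization and without PAPA-NONOate replicate 2, 3, 4 or 8 or any control replicate (adjusted p up to 0.114). SFRP2 lost its call after quantile normalization (adjusted p up to 0.0605). With the replicate number as a block LAMA4, COL18A1 and SFRP2 also lost their calls.

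Among leukocyte markers that fell, CYBB, a subunit of the phagocyte NADPH oxidase, was at 1.41 ± 0.482 against 6.07 ± 0.820 FPKM (SD, n = 5), with a log2 fold change of -1.81 (SE 0.19, adjusted p = 0.000296). PTPRC, the pan-leukocyte antigen, had a log2 fold change of -1.05 (adjusted p = 0.00280), the complement gene C1QB of -1.48 and the myeloid transcription factor gene SPI1 of -0.76. For macrophage and myeloid markers, of 22 measured members 0 rose, 8 fell and 14 did not pass (0 and 13 adjusted over the list alone). Their median was -0.52 relative to all genes (adjusted p = 0.000568 by camera, and adjusted p = 0.740 with an estimated correlation). Only 5 lymphocyte markers were measured, of which CD3E (log2 fold change -1.34, SE 0.28, adjusted p = 0.0117), CD3D (-1.29) and the immunoglobulin joining chain gene JCHAIN (-1.59) fell and 2 did not pass (the same counts adjusted over the list alone), CD3D being named after its value was seen. The list was not called (adjusted p = 0.142 by camera, and adjusted p = 0.822 with an estimated correlation) except without the expression filter or without PAPA-NONOate replicate 4. Erythrocyte and thrombocyte markers were not called as a list (adjusted p = 0.637 by camera, and adjusted p = 0.975 with an estimated correlation). Of 12 measured members 0 rose, 4 fell and 8 did not pass (2 and 4 adjusted over the list alone). The falls included F13A1, a transglutaminase of clotting, at -1.53 and TUBB1 at -0.57. The globin gene HBAD was at 105 ± 27.2 against 54.5 ± 32.4 FPKM (SD, n = 5; adjusted p = 0.0635). It passed after median-ratio scaling, with library weights, with the replicate number as a block, or without PAPA-NONOate replicate 4 or control replicate 5. The list itself passed with the stricter filter or without control replicate 5. JCHAIN lost its call without the expression filter and without control replicate 2 (adjusted p up to 0.0524). TUBB1 lost its call after median-ratio scaling, after quantile normalization and without PAPA-NONOate replicate 4 or control replicate 4 or 5 (adjusted p up to 0.198). With the replicate number as a block TUBB1 also lost its call.

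**Figure D3:**
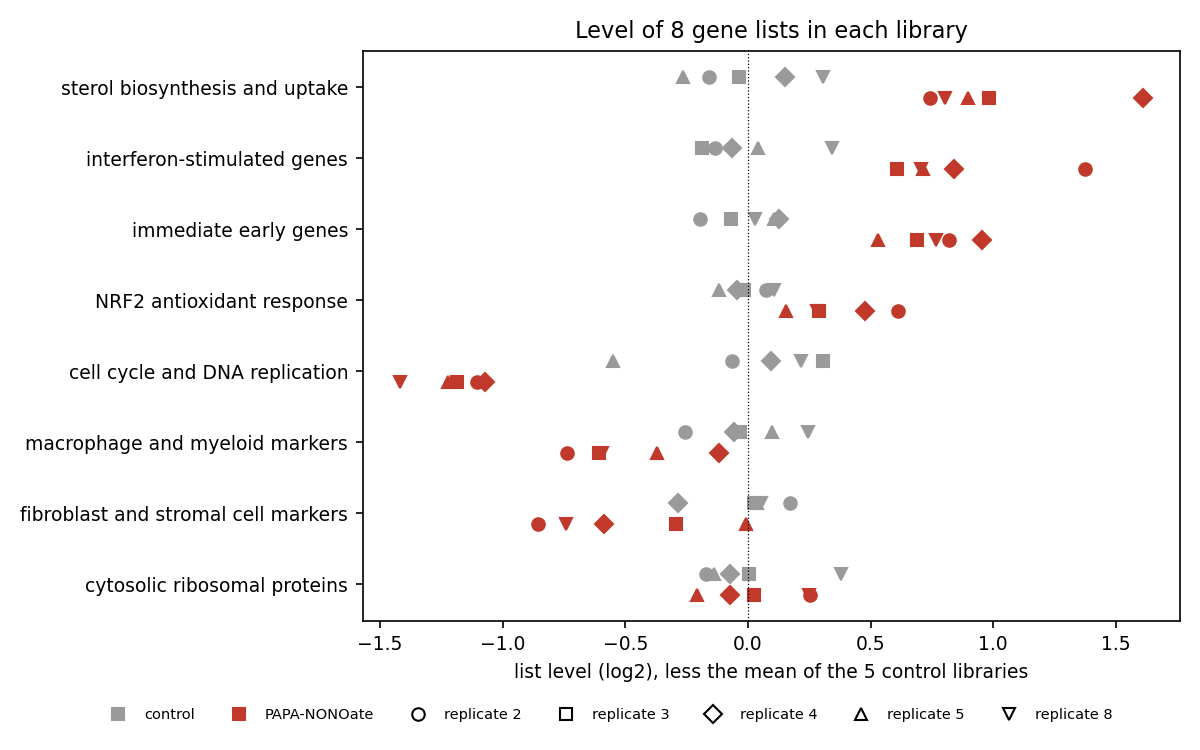
Level of 8 gene lists in each library, as the mean log2(FPKM + 0.5) of the members minus the library's median over all genes tested, less the mean of the 5 control libraries; controls are grey, PAPA-NONOate red, and symbols give the replicate number. The 5 treated libraries lie above all 5 controls for the sterol, interferon, immediate early and NRF2 lists and below them for the cell cycle list, and the groups overlap for the macrophage, fibroblast and ribosomal protein lists.

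Among genes of retinoic acid metabolism, ALDH1A2 (ENSGALG00000004270), which makes retinoic acid from retinaldehyde, was at 300.4 ± 127 against 554 ± 85.5 FPKM (SD, n = 5), with a log2 fold change of -0.99 (SE 0.28, adjusted p = 0.0435). RDH10, which makes retinaldehyde from retinol, was at 21.0 ± 1.30 against 49.6 ± 8.61 FPKM (SD, n = 5), with a log2 fold change of -1.21 (adjusted p = 0.000262). The retinoic acid responsive gene RARRES1 had a log2 fold change of -1.64. Of 16 measured members 1 rose, 4 fell and 11 did not pass (1 and 4 adjusted over the list alone). The rise was that of ALDH1A3 (0.95), named after its value was seen. The list was not called (adjusted p = 0.637 by camera, and adjusted p = 0.975 with an estimated correlation). APOA1, apolipoprotein A-I, was at 853 ± 544 against 1305 ± 422 FPKM (SD, n = 5; log2 fold change -0.76, adjusted p = 0.205) and passed only without PAPA-NONOate replicate 5. In the nitric oxide and cGMP list camera gave an adjusted p = 0.751, and adjusted p = 0.975 with an estimated correlation. Of 21 measured members 0 rose, 2 fell and 19 did not pass (0 and 2 adjusted over the list alone). The 2 were NPR3, the natriuretic peptide clearance receptor (log2 fold change -1.87, SE 0.33, adjusted p = 0.00444), and NOS3, the endothelial nitric oxide synthase, at 8.04 ± 3.47 against 16 ± 4.64 FPKM (SD, n = 5), with a log2 fold change of -1.0 (SE 0.27, adjusted p = 0.0346). NOS2 had a log2 fold change of -0.36, and the guanylate cyclase subunits GUCY1A1 and GUCY1B1 of -0.40 and -0.36, none past the threshold. NOS1 is listed at 0 in 8 of the 10 libraries. For prostaglandin and leukotriene genes camera gave an adjusted p = 0.0969, and adjusted p = 0.862 with an estimated correlation. Of 14 measured members 0 rose, 3 fell and 11 did not pass (1 and 7 adjusted over the list alone), with the receptor gene PTGER4 (-1.35) and the lipoxygenase gene ALOX5 (-1.32) among those that fell. This list passed after quantile normalization, with the replicate number as a block and without PAPA-NONOate replicate 3 or control replicate 2. In the TGF-beta and BMP list camera gave an adjusted p = 0.351, and adjusted p = 0.975 with an estimated correlation. Of 24 measured members 2 rose, 4 fell and 18 did not pass (4 and 5 adjusted over the list alone). INHBB, an activin subunit, fell (log2 fold change -1.16, SE 0.20, adjusted p = 0.00412) and FST, the activin antagonist follistatin, rose (log2 fold change 1.0, SE 0.19, adjusted p = 0.00747). BMP2 was at 68.2 ± 20.7 against 47.1 ± 16.9 FPKM (SD, n = 5; adjusted p = 0.178) and passed only with the replicate number as a block. ALDH1A2 lost its call without the expression filter and without PAPA-NONOate replicate 3, 4 or 8 or any control replicate (adjusted p up to 0.109). NOS3 lost its call without the expression filter and without PAPA-NONOate replicate 3 or 8 or control replicate 2, 4, 5 or 8 (adjusted p up to 0.0809).

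Beyond the fibroblast and macrophage lists, only the Schwann cell list was called by camera among the marker lists of cell types of the choroid and its neighbours. PECAM1, of endothelial junctions, was at 93.5 ± 25.4 against 89.1 ± 14.0 FPKM (SD, n = 5), with a 95% interval of the log2 fold change of -0.34 to 0.43. For endothelial markers camera gave an adjusted p = 0.434, and adjusted p = 0.975 with an estimated correlation. Of 18 measured members 0 rose, 2 fell and 16 did not pass (0 and 2 adjusted over the list alone), the falls being those of the angiopoietin receptor gene TEK (-0.89) and the hyaluronan receptor gene LYVE1 (-0.60). For smooth muscle and pericyte markers camera gave an adjusted p = 0.433, and adjusted p = 0.906 with an estimated correlation. Of 12 measured members 1 rose, 3 fell and 8 did not pass (1 and 4 adjusted over the list alone). CNN1, calponin, rose (log2 fold change 1.46, SE 0.28, adjusted p = 0.00739), CALD1 (-0.72), SMTN (-0.52) and RGS5 (-1.67) fell, SMTN and RGS5 being named after their values were seen, and MYH11 had a log2 fold change of -0.05. None of the 9 melanocyte markers measured passed, as also adjusted over the list alone (adjusted p = 0.687 by camera, and adjusted p = 0.975 with an estimated correlation). Their median was nevertheless -0.98 relative to all genes, with 1 of the 9 above the median of all genes. The level of the list ran from -0.99 to 1.75 among controls and from -1.66 to 1.29 with PAPA-NONOate. In every replicate number it was lower with PAPA-NONOate. TYR, tyrosinase, ranged from 1.13 to 44.2 FPKM among controls and from 0.225 to 15.5 with PAPA-NONOate, and was likewise lower in every number. EDNRB2 had a log2 fold change of -1.29 and KIT of -0.34. EDNRB2 passed with library weights, with the replicate number as a block or without PAPA-NONOate replicate 2. With that block TYR (adjusted p = 0.0118) passed too. So did the melanocyte list, as lower (adjusted p = 0.00185 by camera, and adjusted p = 0.660 with an estimated correlation). For retinal pigment epithelium markers camera gave an adjusted p = 0.637, and adjusted p = 0.889 with an estimated correlation. Of 7 measured, ENPP2 (-1.27) and LRAT (-0.96) fell and 5 did not pass (the same counts adjusted over the list alone). RPE65 itself was at 0.101 ± 0.0980 against 0.0984 ± 0.0879 FPKM (SD, n = 5). The retina list had 1 measured marker, GLUL (-0.04). Of the 3 scleral cartilage markers measured none passed, with SOX9 at 0.89 and COL2A1 at -0.33. SOX9 passed with library weights or without PAPA-NONOate replicate 2. For neuron markers camera gave an adjusted p = 0.947, and adjusted p = 0.975 with an estimated correlation. Of 13 measured members 1 rose, 1 fell and 11 did not pass (1 and 1 adjusted over the list alone). UCHL1 rose (log2 fold change 1.53, SE 0.22, adjusted p = 0.00179) and NEFL, a neurofilament, fell (-1.27). None of the 11 Schwann cell markers passed singly, also adjusted over the list alone, with FOXD3 at -0.57 and MBP at 0.51. That list was called higher as deposited (adjusted p = 0.0427 by camera, and adjusted p = 0.822 with an estimated correlation). That call was lost after median-ratio scaling (adjusted p = 0.168), after quantile normalization, without the expression filter, with library weights, and without PAPA-NONOate replicate 2 or 8 or control replicate 2, 3 or 4 (adjusted p up to 0.273). FOXD3 passed with library weights or with the replicate number as a block. TEK lost its call with a pseudocount of 0.1, without the expression filter, after quantile normalization and without PAPA-NONOate replicate 2, 3 or 8 or control replicate 2, 4, 5 or 8 (adjusted p up to 0.0889). LYVE1 lost its call with a pseudocount of 0.1, without the expression filter, with the stricter filter, after median-ratio scaling, after quantile normalization and without PAPA-NONOate replicate 2, 3 or 8 or control replicate 2, 3, 4 or 5 (adjusted p up to 0.134). CALD1 lost its call without the expression filter and without PAPA-NONOate replicate 2, 3, 4 or 8 or control replicate 2, 3, 4 or 8 (adjusted p up to 0.103). LRAT lost its call after quantile normalization and without PAPA-NONOate replicate 4 or 8 or control replicate 2 or 8 (adjusted p up to 0.0602). With the replicate number as a block TEK and CALD1 also lost their calls.

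Among lists of general metabolism none was called. Of 23 genes of hypoxia and glycolysis (adjusted p = 0.947 by camera, and adjusted p = 0.975 with an estimated correlation), the glycolytic enzyme gene TPI1 fell (-0.62) and 22 did not pass, PDK3 at -0.36 among them, and none passed adjusted over the list alone. After median-ratio scaling 3 of the 23 rose and 0 fell. None of 35 nuclear-encoded genes of oxidative phosphorylation, of 40 cytosolic ribosomal proteins or of 13 mitochondrially encoded transcripts passed by limma, over all genes or adjusted over the list alone. For the phosphorylation list camera gave an adjusted p = 0.842, and adjusted p = 0.975 with an estimated correlation. For the ribosomal proteins it gave an adjusted p = 0.751, and adjusted p = 0.975 with an estimated correlation, and for the mitochondrial transcripts an adjusted p = 0.483, and adjusted p = 0.975 with an estimated correlation. Their members with the smallest adjusted p were NDUFS1 (-0.40) and COX5A (-0.42), RPL15 (-0.42) and RPL30 (-0.34), and MT-CO1 (-0.54) and COII (-0.38), with log2 fold changes in parentheses. PDK3 and MT-CO1 passed with library weights. For iron and metal handling camera gave an adjusted p = 0.698, and adjusted p = 0.975 with an estimated correlation. Of 17 measured members 0 rose, 2 fell and 15 did not pass (1 and 3 adjusted over the list alone), the falls being those of the metallothionein gene MT4 (-1.13) and the heme exporter gene FLVCR1 (-0.68). TPI1 lost its call without the expression filter, after median-ratio scaling and without PAPA-NONOate replicate 2, 3 or 4 or control replicate 2, 4, 5 or 8 (adjusted p up to 0.0926). MT4 lost its call without the expression filter and without PAPA-NONOate replicate 8 or control replicate 2, 4, 5 or 8 (adjusted p up to 0.0850). FLVCR1 lost its call with a pseudocount of 0.1, without the expression filter, with the stricter filter and without PAPA-NONOate replicate 2, 3, 4 or 8 or any control replicate (adjusted p up to 0.122). With the replicate number as a block FLVCR1 also lost its call.

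Of 34 gene lists 32 had at least 5 measured members, and 13 of them passed camera with its preset correlation of 0.01, 9 higher and 4 lower, or 2 lower without PAPA-NONOate replicate 8 or control replicate 5. No call held with a correlation estimated for each list, for which the lowest adjusted p was 0.14. In fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, 5 lists passed: the interferon and immediate early lists higher, and the cell cycle, macrophage and retinal pigment epithelium lists lower. The last of these, with 7 measured members, had a median of -0.22 as deposited but of only -0.05 relative to all genes. Camera did not call it (adjusted p = 0.637). In an exact permutation test of the list level per library, two-sided and chosen after the data were seen, 12 lists passed (n = 5 per group). They were 11 of the 13, all but the matrix and Schwann cell lists, and the lymphocyte list, with adjusted p-values of 0.0317 where the groups did not overlap and 0.0423 otherwise. The direction of camera is relative to other genes: it was up for the unfolded protein, matrix protease, hypoxia, TGF-beta, endothelial, smooth muscle, erythrocyte and neuron lists, none of them past the threshold, although their median and mean log2 fold changes as deposited were below 0. The medians of the unfolded protein, matrix protease, hypoxia, TGF-beta and neuron lists also lay below that of all genes (by -0.31 for the neuron list). For these lists the direction of camera does not follow from the medians.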

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

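No test in this part was added after the results were seen. In 20 (7.94%) of the groups of 5 libraries looked at, the highest or lowest library lay apart from the others. Its gap to the next library was more than 0.71 of the range of its group, where chance gives about 1 in 20. Gap and range were taken on the log2 scale of the limma test, and on the FPKM scale other libraries would be flagged. The values printed are FPKM, with the range of the other 4 libraries of the group in parentheses. Of the 20, 8 were in PAPA-NONOate libraries, 5 of them in replicate 4, and 12 in controls, 5 of them in replicate 8; the other libraries had 0 to 2 each. Among genes that rose these were STEAP4 in PAPA-NONOate replicate 4 at 10.1 (below 24.8 to 30.3), IFI6 in control replicate 8 at 3.80 (above 1.26 to 1.69), MX1 in control replicate 8 at 2.48 (above 0.581 to 0.757) and TXNRD1 in control replicate 2 at 30.6 (above 14.6 to 17.7). In BAG3 and FDFT1 a treated library stood highest: BAG3 in PAPA-NONOate replicate 4 at 98.1 (above 81.0 to 85.3) and FDFT1 in PAPA-NONOate replicate 4 at 20.2 (above 8.68 to 9.60). Among genes that fell there were RRM2 in PAPA-NONOate replicate 8 at 2.0 (below 3.40 to 3.66), MCM3 in control replicate 5 at 3.38 (below 6.63 to 7.91) and INHBB in control replicate 8 at 19.1 (above 10.6 to 11.3). Stromal and blood cell genes included SFRP2 in control replicate 8 at 6.29 (above 5.30 to 5.54), C1QB in control replicate 8 at 128 (above 50.6 to 62.1), JCHAIN in control replicate 3 at 6.50 (below 14.0 to 15.5) and TUBB1 in control replicate 5 at 6.39 (above 4.55 to 5.01). Among genes not called were NDUFS1 in PAPA-NONOate replicate 2 at 6.71 (below 9.36 to 10.6) and PDGFD in PAPA-NONOate replicate 4 at 70.3 (above 43.4 to 46.1). Also not called were COII in PAPA-NONOate replicate 4 at 7466 (above 5472 to 5722), VEGFA in control replicate 4 at 313 (above 199.7 to 216) and PECAM1 in control replicate 4 at 114 (above 81.0 to 84.6). NOS1 was listed above 0 in 1 library of each group, at 0.0188 FPKM in control replicate 3 and 0.0602 in PAPA-NONOate replicate 3.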

How the results depend on the processing

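Median-ratio scaling combined with a left-out library or with the block, the block with an estimated correlation, and the permutation test of list levels, were chosen after the data were seen. No named gene or list reversed its direction while called. Of 87 called named genes 65 kept call and direction in limma under those of the 21 settings run per gene in which they could be tested, and 22 lost the call under at least 1; of 32 not called, 15 gained a call under at least 1. Of 13 called lists 7 kept their call under every setting of camera with the preset correlation. The filter at 5 FPKM, which tests fewer genes, gave 605 changed genes, 449 lower, and 215 at least 2-fold, 54 higher and 161 lower. Median-ratio scaling gave 790 higher and 149 at least 2-fold higher, and quantile normalization 733 higher, 163 at least 2-fold higher and 201 at least 2-fold lower. Both move the median of all genes from -0.18 to near 0. With median-ratio scaling 5 heat shock chaperones rose and 0 fell, against 2 and 1 as deposited. For the endothelial list 3 rose and 1 fell, against 0 and 2, and for the nitric oxide list 2 and 2, against 0 and 2. The cell cycle list kept its counts of 0 and 22. Library weights gave 1807 changed genes, 383 higher and 1424 lower, and 2 lists lower. With median-ratio scaling and PAPA-NONOate replicate 2 left out, 659 genes were higher and 194 at least 2-fold lower. With 1 library left out, changed genes numbered 604 to 1813, higher 158 to 254, lower 429 to 1580, at least 2-fold 338 to 621, 2-fold higher 81 to 104, 2-fold lower 257 to 517, lists 10 to 14, lists higher 8 to 10 and lists lower 2 to 5. The exact Wilcoxon test called 0 genes, 0 higher and 0 lower, with 2352 at an unadjusted p under 0.05 (3194 by limma); its smallest exact p for 5 against 5 is 0.00794, and the lowest adjusted p was 0.0852. Camera with an estimated correlation called 0 lists, 0 higher and 0 lower, and fry 5, of which 2 were higher. Other than where the construction shows it, the cause was not tested. Depth limits single weak genes, and its absolute size is unknown.

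The labels do not say that equal replicate numbers mark paired samples. If they do, the fit with the block would be the better one, and the main fit ignores the pairing. Correlations of the deviations of same-numbered libraries were 0.00, 0.29, 0.30, -0.02 and 0.19 for numbers 2, 3, 4, 5 and 8, and 6 of 10 libraries correlated best with their own number. With the replicate number as a block, 893 genes were changed, 213 higher and 680 lower, and 15 lists, and of the named genes 11 lost and 6 gained a call. The lists gained were those of melanocyte markers (adjusted p = 0.00185, and adjusted p = 0.660 with an estimated correlation) and prostaglandin genes (adjusted p = 0.0416, and adjusted p = 0.829 with an estimated correlation). The named genes gained were TYR (adjusted p = 0.0118), EDNRB2 (adjusted p = 0.00308), HMOX1, BMP2, HBAD and FOXD3. In every replicate number TYR, EDNRB2 and FOXD3 were lower, and HMOX1, BMP2 and HBAD higher, with PAPA-NONOate than in the control. A call with the block favours such genes. The named genes lost were NQO1, CAT, BAG3, CCNG1, LAMA4, COL18A1, TEK, CALD1, SFRP2, TUBB1 and FLVCR1. With the block and an estimated correlation 0 lists were called, 0 higher and 0 lower. The block with quantile normalization gave 1675 changed genes, 835 higher, 175 at least 2-fold higher and 217 at least 2-fold lower, and the block with median-ratio scaling 1890, 927 higher and 153 at least 2-fold higher.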

Other observations

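Genes in this paragraph were chosen from the whole table after their values were seen. Further genes were higher with PAPA-NONOate: ESM1, an endothelial proteoglycan, had a log2 fold change of 1.87 (SE 0.14, adjusted p = 3.01e-05), EDN2, an endothelin, a log2 fold change of 1.55 (adjusted p = 0.00150), and HBEGF, a growth factor of the EGF family, of 1.11 (adjusted p = 0.000828). The peptide precursor genes PENK and CCK had log2 fold changes of 1.15 and 1.17, and the prohormone convertase gene PCSK1 of 1.20 (adjusted p = 0.00385, 0.0152 and 0.00199). CYP24A1, which breaks down vitamin D, was lower, with a log2 fold change of -1.91 (SE 0.21, adjusted p = 0.000312). So were WNT4 (-1.90), PTHLH (-1.88), the guidance gene NTN1 (-1.75) and the potassium channel gene KCNJ8 (-1.62), with adjusted p-values of 0.000734, 0.00277, 0.00212 and 0.00637. GCHFR, a regulator of the enzyme that makes tetrahydrobiopterin, a cofactor of nitric oxide synthases, had a log2 fold change of -1.6 (SE 0.37, adjusted p = 0.0184).

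The tests of library scaling, of the leukocyte share and of the interferon level per library were chosen after the results were seen. As deposited, 79.4% of calls were lower. After median-ratio scaling the share was 48.7%, but this scaling centres the fold changes (median of all genes -0.18 before), which fixes a share near 50% in advance, so that the share decides nothing about library scaling. Genes called at least 2-fold lower still outnumbered those at least 2-fold higher after it, 236 against 149, and whether scaling accounts for the excess stays open. Without PAPA-NONOate replicate 2, the library with the lowest summed FPKM, the share was 71.4%, which argues against that library alone as the cause. FPKM are relative values, and a change in the amount of RNA per cell was not tested.

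Neither scaling nor PAPA-NONOate replicate 2 accounted for the lower cell cycle list: its median log2 fold change was -1.09 after quantile normalization, against -1.33 as deposited, and -1.19 relative to all genes without PAPA-NONOate replicate 2, against -1.16 with it. A lower rate of cell division with PAPA-NONOate is a candidate explanation, as a hypothesis that EdU incorporation in treated and control choroids would test. What the letters R and L mark is confounded with the treatment and stays open, here and for every difference between the groups.

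A higher share of leukocytes would raise their markers along with interferon-stimulated genes, but the level of macrophage and lymphocyte markers was lower with PAPA-NONOate, by a log2 difference of -0.52 (27 markers, exact two-sided permutation p = 0.0159, n = 5 per group). Without PAPA-NONOate replicate 2 camera with its preset correlation still called the interferon list (adjusted p = 2.79e-13). With all libraries camera gave an adjusted p = 7.70e-17, and adjusted p = 0.14 with an estimated correlation. Calls with the preset correlation are, however, also frequent in other splits of the libraries and are not counted here. The level of the list per library was higher in each of the other 4 treated libraries than in every control, by a mean log2 difference of 0.72 (exact two-sided permutation p = 0.0159, n = 4 and 5). The marker level and the list level argue against a higher leukocyte share and that library as the whole cause, and a response of the resident cells to nitric oxide may remain, as a hypothesis. In situ hybridization of IFIT5 with macrophage markers, in choroids given fresh or fully decayed donor, would test it.

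Of 100 splits of the 10 libraries into 5 and 5, only the real 1 gave as many changed genes (1061, with 12 as the highest of the others) or as many changed at least 2-fold (435, with 12). A chance split is thus an unlikely source of these counts, to the 1 in 100 that this number of splits can resolve. As many lists as the 13 were called in 21 of the 100 splits, with 15 as the highest of the others, so that chance is not excluded for the number of lists that camera calls with its preset correlation. Some of the other splits kept 4 of the 5 treated libraries together, so the 21 is not a measure of chance alone. A split with 2 treated libraries in its first group also reached 15.

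Whether neighbouring genes were called higher together was also tested. Of 3814 adjacent pairs, 1 had both genes called higher, CMPK2 and RSAD2, against a mean of 0.973 over shuffled gene orders (one-sided permutation p = 0.629), so that no clustering was detected.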
